A study of Homo sapiens with 18 samples.

How the data were processed

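The samples were HEK293T cells in 15 cm dishes transfected with 40 µg of plasmid and harvested after 72 hours, per the labels' protocols. Chromatin was fixed with formaldehyde, sonicated and precipitated with an anti-FLAG antibody. Of the 18 samples in the series, 9 carried an antibody label and a peak list, 3 for each of 3 crRNAs. The other 9 were labelled as made without antibody and had no peak list, and they were not analysed here. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says whether replicates were separate transfections, so p-values measure only the spread between these samples, which may be technical.

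The authors deposited 1 peak list per sample, so peaks were called in each sample by itself and not on pooled samples. The submitters' processing notes name the trimmer Trimmomatic 0.32, the aligner Bowtie 1.0.0, Picard, the peak caller MACS2 2.1.0.20151222, bedtools 2.25.0 and the genome build hg38, without their order or settings, and tools for read counting whose output was not used here. The peak names contain words for removed duplicates and for masking, but what was masked is not given in the sources used here, nor is the control that the peak caller used. A region that was masked cannot hold a peak, and a control that differs between samples would change the number called. Each deposited peak has a fold enrichment over the local background, which is a ratio and the peak's own value in its list. The deposited lists also give the −log10 of the p-value and of the q-value of each peak. The deposited score is the −log10 q value multiplied by 10 and truncated to a whole number, as found in every row, and was not used further. The last deposited column, of another kind (the distance of the summit from the start of the peak in bp), placed the summits. The lowest −log10 q in a list was between 1.31 and 1.39. The peak lists give no counts, so the depth of a sample is unknown and no interval that needs it is given. Scores and ranks belong to their own list and were used only to describe, rank or filter peaks within it, while samples were compared by whether a region was called.

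Peaks that overlapped by at least 1 bp in any samples were merged into regions, and a region was called in a sample when that sample had a peak in it. No peak was identical between any of 36 pairs of lists, so every sample was counted as its own. Gene positions came from a RefSeq gene table of the same build, with 59716 genes. It gives the start and end of each gene but no strand, transcripts or start sites, and no genome sequence came with it. The design had named start sites. They were replaced by the extent of the gene widened by 5 kb on each side for the target genes, and by a distance of 1 kb from either gene boundary for the share of peaks near genes and for the gene lists, except that the zinc-finger list used the gene body. A match of the crRNAs to the genome, with their protospacer motifs, could not be made. HBE was read as HBE1 through the synonyms in the table.

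The tests were fixed before the data were examined. The presence of a peak at the target gene was compared by exact one-sided permutation over all splits of the samples, 84 for 3 against 6 and 20 for 3 against 3, with smallest p-values of 0.0119 and 0.05. Log2 peak number and the share of peaks near gene boundaries were compared between crRNAs by an exact permutation test of the share of variance explained, over the 280 partitions of 9 samples into 3 groups of 3. The Jaccard index was compared within against between crRNAs over the same partitions. Regions called in all samples of a crRNA and in no other were counted for the real split and for every other split. Shares near gene boundaries were set against 100 random placements of the summits over the annotated span of their chromosomes, with seed 11. Assembly gaps and masked sequence inside that span were not left out, which can raise the ratio to random positions. Gene lists were tested by Fisher's exact test, one-sided, against the other genes of the same classes, with Benjamini-Hochberg adjustment over 10 lists and a threshold of 0.05. Neighbouring genes can share a peak, so the genes in that test are not fully independent.

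The genes and regions named were chosen by a rule: the target genes and their clusters, up to 20 regions specific to each crRNA and the 10 best regions called in all 9 samples, both by mean rank, and up to 4 members per gene list called in at least 2 of 3 samples of every crRNA. A region was named by the gene that holds its summit, or else by the nearest boundary. Some regions that the rule names are not reported here. The 3 further histone genes were named to complete a count after their values were seen. The alternatives were stricter q values, equal list lengths of 686 peaks (the shortest list), wider or narrower windows, other ways of merging, leaving out each replicate in turn, and permuting only within replicate numbers. Leaving out a sample also changed the rule of a count. Counts that asked for every sample then asked for fewer calls or fewer absences. Counts in at least 2 of 3 samples then asked for both remaining samples of that crRNA. Alternatives added after the data were seen were the comparison of all 6 IL1RN samples with HBE, a strict q value with full absence elsewhere, a comparison between the IL1RN crRNAs alone, lists shortened to the 1507 peaks of the shortest HBE list, the 8 or 7 longest lists taken at one length, local shifts of 0.1 to 1 Mb in place of random positions, and the gene lists without each replicate. The Jaccard comparisons of HBE with IL1RN and of the IL1RN crRNAs alone were also chosen after the data were seen.

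The code was tested on simulated lists with the real list lengths. It found 20 of 20 planted HBE regions, 5 of 5 planted regions of the IL1RN samples and 0 regions for crRNA 25, where none was planted, in a run of 15390 regions. With peaks planted at 12 histone genes, 19 were called, because neighbours within 1 kb share a peak, and 1 of the 10 lists passed. Calculations used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.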

Results

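The series mapped where the Cascade complex of a type I CRISPR-Cas system was found along the genome of HEK293T cells, a transformed human embryonic kidney line that transfects easily. Cascade is a complex of several proteins that carries a CRISPR RNA (crRNA) and binds DNA matching it. Cells received plasmids for Cascade and for 1 of 3 crRNAs, and chromatin was precipitated with an antibody against the FLAG tag. One crRNA was named for HBE, read here as HBE1, the embryonic epsilon-globin gene. The other crRNAs, numbered 25 and 26, were named for IL1RN, which encodes the antagonist of the interleukin-1 receptor. Each crRNA had 3 anti-FLAG samples with a list of peaks, and the 9 samples made without antibody had no list and were not analysed here. The lists held 17860 peaks, which merged into 6631 separate regions. They give no read numbers, so the depth of each sample is unknown and the absence of a peak means only that none was called.

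The comparison at the target genes asked whether each crRNA brought Cascade to the gene it was named for. Both IL1RN crRNAs gave a peak inside IL1RN in 3 of 3 samples, and no HBE sample had one. IL1RN (gene ID 3557) spans chromosome 2 from 113099360 to 113134014 in hg38, and the peaks of the 6 samples together covered 113117620 to 113118177, inside the gene. The fold enrichment given by the authors' peak caller was 36 ± 11.4 (SD, n = 3) with crRNA 25 and 24.5 ± 8.14 (SD, n = 3) with crRNA 26. The peak ranked 1 by q value in all lists of crRNA 25 and in replicates 1 and 3 of crRNA 26, and ranked 3 in replicate 2 of crRNA 26. With 3 samples against the 3 HBE samples, an exact one-sided permutation test gave p = 0.05 for each IL1RN crRNA, the smallest value that 20 splits allow. Taken as 6 samples against 3, a comparison chosen after the data were seen, the exact permutation p was 0.0119.

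The summits of the 6 IL1RN peaks lay within 9 bp of one another, although the samples carried differently numbered crRNAs. With crRNA 25 they fell between positions 113117893 and 113117896, and with crRNA 26 between 113117890 and 113117899. Their mean positions differed by 0 bp (exact two-sided permutation test, p = 1, 20 splits). The summit of replicate 1 of crRNA 25 lay 18536 bp above the lower end of the gene and 16118 bp below its upper end. Exons and transcription start sites were not available in the annotation used here, so whether the peak meets an exon, an intron or an internal start site was not determined.

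**Figure D1:**
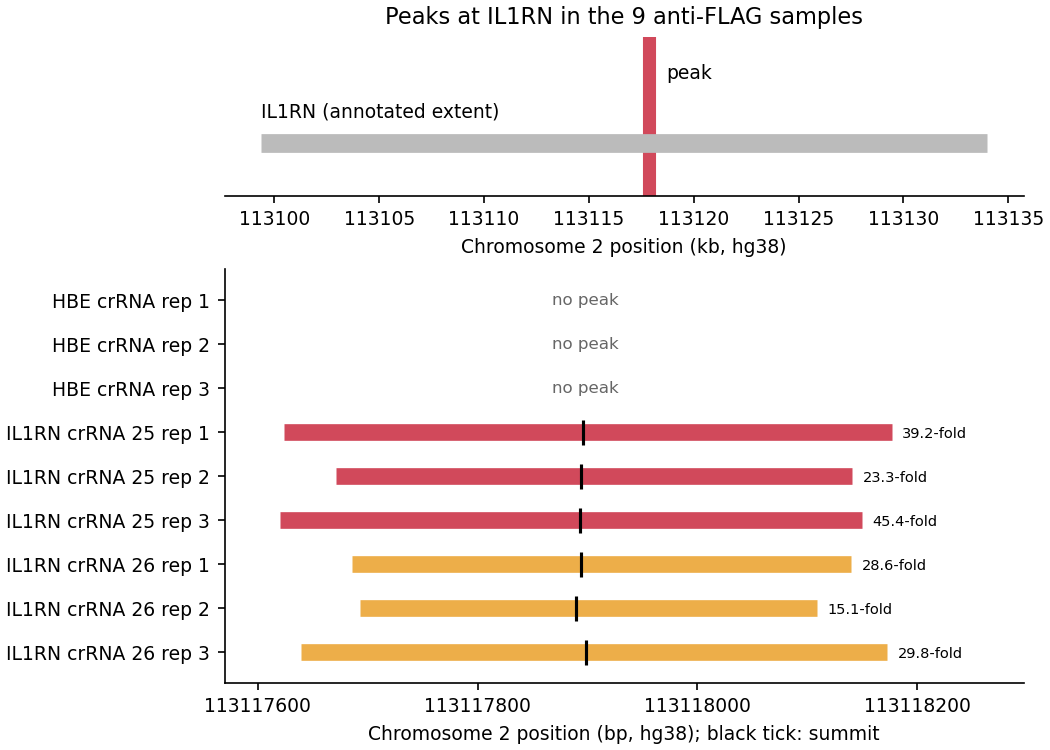
Upper panel, the annotated extent of IL1RN on chromosome 2 (kb, hg38) with the merged peak region in red. Lower panel, the called peak of each of the 9 anti-FLAG samples (bars, position in bp) with its summit (black tick) and the fold enrichment given by the peak caller, from 15.1 to 45.4 in the 6 IL1RN samples; the 3 HBE samples had no peak there.

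HBE1 had no peak in any of the 9 lists, the 3 HBE samples included. The gene (gene ID 3046) spans chromosome 11 from 5268345 to 5269945, at the end of the β-globin cluster, and no summit lay within 5 kb or within 50 kb of it. The nearest called summit in the HBE samples was 660 kb away, and the same was true of 3 of the 6 IL1RN samples. No member of the β-globin list, which holds HBE1, HBG1, HBG2, HBD and HBB, was called in any sample. The exact permutation test of HBE against IL1RN samples gave p = 1 (one-sided, 84 splits), because all values were 0.

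**Figure D2:**
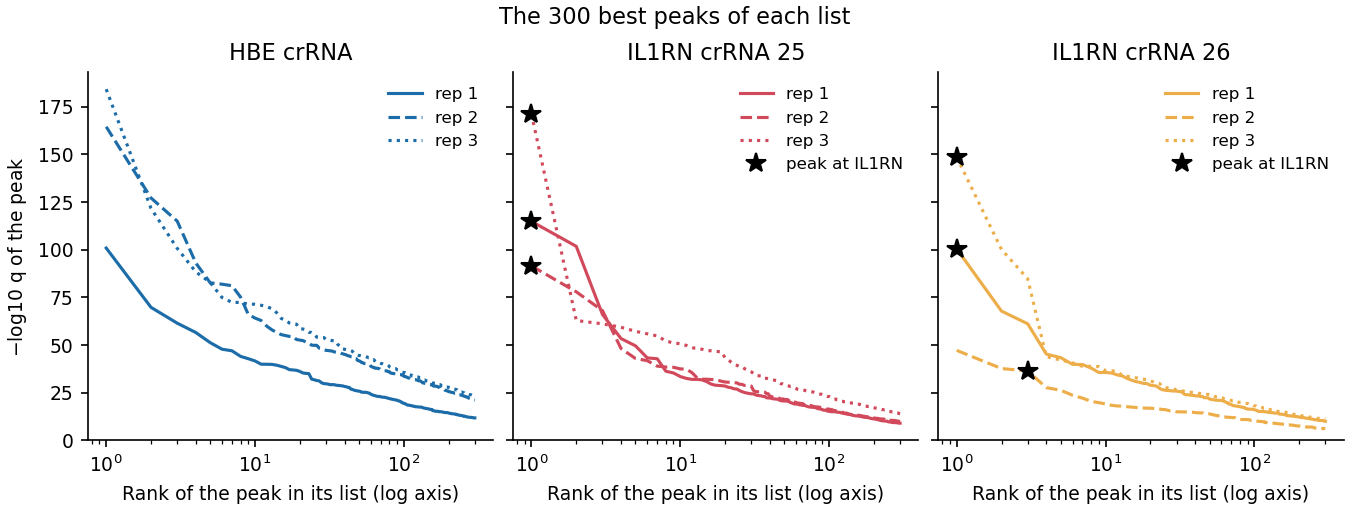
The −log10 q value (vertical axis) of the 300 best peaks of each sample against their rank in the list (horizontal log axis), 1 panel per crRNA and 1 line per replicate. Stars mark the peak at IL1RN, at rank 1 in 5 of the 6 IL1RN lists and at rank 3 in the sixth; the HBE lists have none.

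The number of peaks called was compared between the crRNAs next. It also depends on depth and on the control used for calling, both unknown here, so it does not measure the yield of a precipitation. HBE samples had 3318 ± 1598 peaks (SD, n = 3), samples of crRNA 25 had 1458 ± 517 (SD, n = 3) and samples of crRNA 26 had 1177 ± 448 (SD, n = 3). The 3 crRNAs did not separate beyond the spread between replicates, since the crRNA accounted for a share of 0.551 of the variance of log2 peak number (exact permutation test over the 280 partitions, p = 0.0893). In pairs, HBE exceeded crRNA 25 by 2.13-fold and crRNA 26 by 2.69-fold in geometric means (exact two-sided permutation tests, p = 0.2 for both, adjusted p = 0.3 over 3 pairs, smallest possible p = 0.1). Replicate 1 of HBE, with 1507 peaks, stood nearer the IL1RN samples than replicates 2 and 3, with 4531 and 3917. Without it the share of variance was 0.791 (exact permutation test, p = 0.0321).

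**Figure D3:**
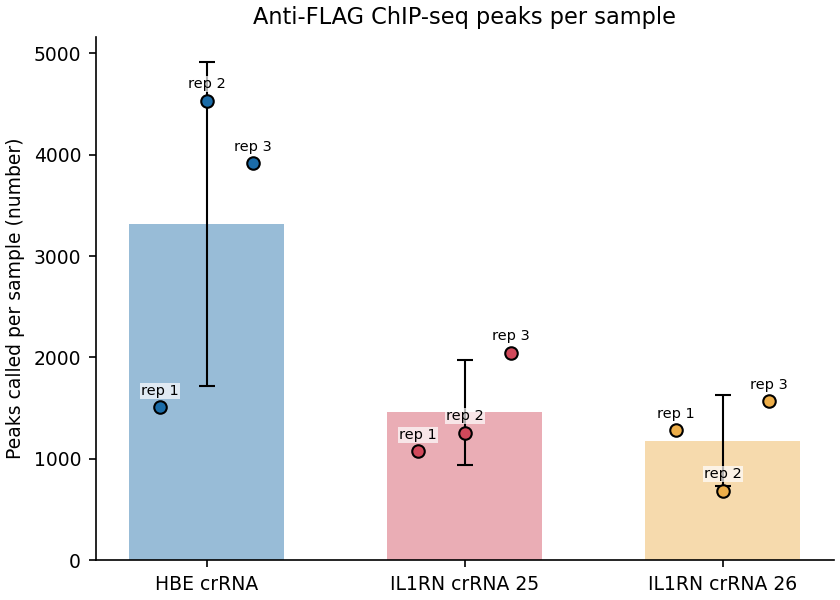
Peaks called per sample (points, labelled by replicate) with the mean (bars) and SD (error bars) of each crRNA, n = 3. HBE replicates 2 and 3 have 4531 and 3917 peaks, and the other 7 samples lie between 686 and 2046.

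Regions that followed the crRNA across the genome were sought next. IL1RN was the single region called in all 6 IL1RN samples and in 0 of 3 HBE samples. As many were found in 44 of the 84 splits of 6 against 3 samples, and the highest other gave 20. That split took the long lists of replicates 2 and 3 of HBE among its 6 samples. List length thus enters the comparison, and it does not decide whether a count of 1 is unusual. When a −log10 q of at least 10 was asked in each of the 6 samples, a criterion added after the data were seen, IL1RN was still the only region and no other split gave any. With crRNA 25, 3 regions were called in 3 of 3 samples and in 0 of 6 others, and 29 of 84 splits gave as many. They lay in MTRES1 (chromosome 6, 107028052 to 107028540), in RAP1GAP2 (chromosome 17, 2892346 to 2892847) and 6566 bp from LOC124905041 (chromosome 21, 45364025 to 45364461), and their mean fold enrichments were 4.40 ± 0.69, 4.82 ± 1.14 and 5.51 ± 0.81 (SD, n = 3). With crRNA 26 no region met the criterion. These small counts moved when a sample was left out, which also loosens the rule, as fewer calls or fewer absences are then asked. For crRNA 25 the count became 12 and 14 without its replicates 1 and 2. For crRNA 26 it became 3, 6 and 1 without its replicates 1, 2 and 3, and 1 without replicate 3 of HBE. For both IL1RN crRNAs it became 5 and 2 without replicates 2 and 3 of crRNA 26, and 2 without replicate 2 of HBE. Between the IL1RN crRNAs, 17 regions were called in 3 of 3 samples of crRNA 25 and none of crRNA 26, and 6 regions the other way round (exact permutation tests over 20 splits, p = 0.35 and p = 0.7).

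The HBE samples shared 150 regions that no IL1RN sample had. Only the real split gave so many among the 84 splits of 3 against 6, and the highest other gave 98. Of the 150, 0 stood among the 10 best peaks of all 3 HBE lists. The best placed, with a mean rank of 204, lay 76 bp from HNRNPD-DT, a transcript divergent from the RNA-binding protein gene HNRNPD (chromosome 4, 82374150 to 82374770), at a fold enrichment of 8.75 ± 3.06 (SD, n = 3). Next came regions in LOC105372841 (7.59 ± 1.61), 894 bp from the serine tRNA gene TRS-GCT5-1 (7.59 ± 2.63), 264 bp from the magnesium transporter gene NIPA2 (8.61 ± 2.33) and 3072 bp from HES1, a transcriptional repressor of the Notch pathway (8.64 ± 2.21). Others among the 20 best placed lay in PELO, in ITGB3, which encodes an integrin, in the thyroid hormone receptor gene THRB, and in PHACTR2, SPEN-AS1, LINC01011, B4GALT6, DST, SSPN, CDC42BPB and CDC42BPA. The remaining 4 of the 20 lay near ZNF969P, LINC01605 and the tRNA genes TRQ-CTG6-1 and TRL-CAA1-2. Of the 150 regions, 5 had a −log10 q of at least 10 in each HBE sample, at HNRNPD-DT, LOC105372841, HES1, THRB and PHACTR2.

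The count of HBE regions depended on the lists it was taken from. Without replicate 1 of HBE, when only its replicates 2 and 3 had to agree, it was 693. Without replicate 2 or 3 of HBE it was 194 and 190. With the 686 best peaks of every sample it was 12, with 7 as the highest other split. Of those 12, 2 had no peak in the whole IL1RN lists.

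**Figure D4:**
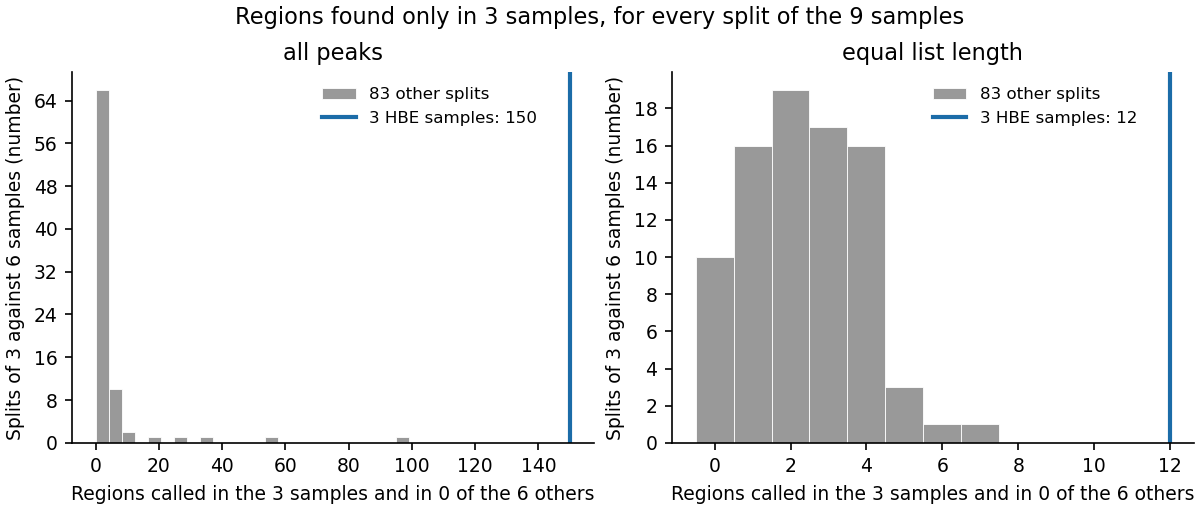
Number of splits of the 9 samples into 3 against 6 (vertical axis) by the number of regions called in the 3 samples and in none of the 6 (horizontal axis), for all peaks (left) and for the 686 best peaks of each sample (right). Grey bars are the 83 other splits, and the line is the split that takes the 3 HBE samples, at 150 and at 12 regions.

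Most regions called in every replicate of a crRNA were called in at least 1 sample of another crRNA. In all 3 replicates, HBE had 1132 regions, crRNA 25 had 583 and crRNA 26 had 442, of which 86.7%, 99.5% and 100% were so called. Fewer were called in all replicates of another crRNA: of the HBE regions, 41.3% with crRNA 25 and 33.7% with crRNA 26, and of the regions of crRNA 25 and crRNA 26, 80.3% and 86.4% with HBE. A set of 319 regions was called in all 9 samples, and 702 in at least 2 of 3 samples of every crRNA. Without replicate 1 or 3 of crRNA 26, when both of its remaining samples had to agree, the 702 fell to 459 and 431. The best ranked of the 319 lay in the immunoglobulin heavy chain locus IGH on chromosome 14, from 105857261 to 105860701, with a mean rank of 1.67 and a fold enrichment of 25.7 ± 12.1 (SD, n = 9). Another IGH region, from 105710304 to 105712604, came next at 22.2 ± 8.34 (SD, n = 9). Others of the 10 best lay in ARPIN-AP3S2, a readthrough of neighbouring genes (12.1 ± 5.47), and in the glycogen phosphatase gene EPM2A (8.62 ± 1.24). Further ones lay in LINC01237, the linker histone gene H1-2, TNPO1-DT and C1QTNF8, with fold enrichments from 11.6 ± 4.71 to 15.1 ± 3.23.

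Samples of the same crRNA shared slightly more of their regions than samples of different crRNAs, by an amount that depended on list length. The mean Jaccard index, the share of the regions of a pair of samples that both called, was 0.360 ± 0.057 (SD, 9 pairs) within crRNAs and 0.314 ± 0.087 (SD, 27 pairs) between them. The difference of 0.0460 did not pass the exact one-sided permutation test (p = 0.0714). With the 686 best peaks of each sample it was 0.0382 (exact permutation p = 0.00357), and without replicate 1 of HBE it was 0.0795 (exact permutation p = 0.0393). At equal length the HBE samples were closer to one another (0.449 ± 0.022) than to samples of crRNA 25 (0.359 ± 0.014) or crRNA 26 (0.374 ± 0.021), a difference of 0.0828 that was tested after it was seen (exact one-sided permutation test over 84 splits, p = 0.0119). With all peaks that difference was 0.0504 (exact one-sided permutation p = 0.19). For the IL1RN crRNAs alone, the index within minus between them was 0.0081 at equal length (exact one-sided permutation p = 0.1, the smallest that their 10 distinct splits allow) and −0.0126 with all peaks (exact one-sided permutation p = 1).

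**Figure D5:**
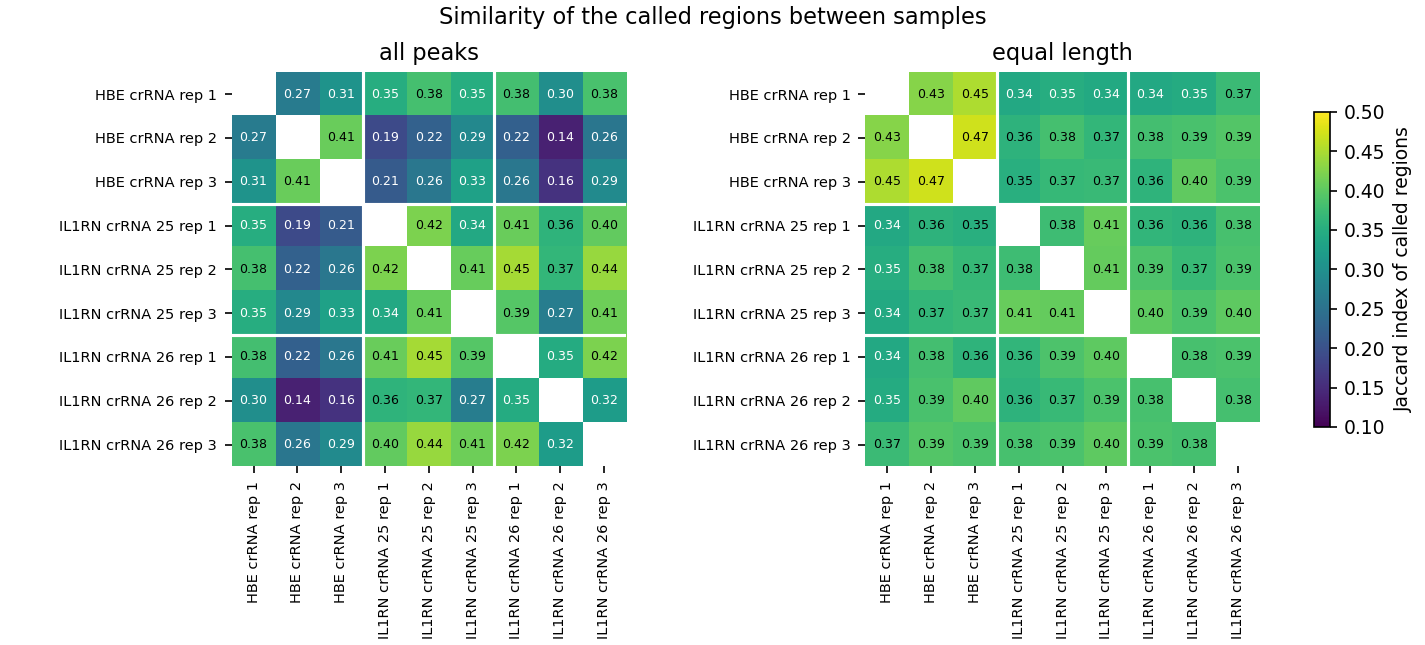
Jaccard index of the called regions for each pair of the 9 samples (colour and printed value), for all peaks (left) and for the 686 best peaks of each sample (right), with lines between the crRNAs. At equal length the 3 pairs of HBE samples have the highest values, from 0.427 to 0.471.

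Of the 6631 regions, 55.1% lay within 1 kb of an annotated gene boundary. Averaged over the 9 samples, 67.4% ± 4.47 (SD, n = 9) of peaks, which count a shared region once per sample, had their summit that near, 10.7 ± 0.87 times the share at random positions of the same chromosomes. Assembly gaps were not left out of those positions, and local shifts of the summits gave a ratio of 8.09. In each of the 9 samples the share was above all 100 random placements. It was 62.9% ± 5 in HBE, 69.1% ± 2.31 with crRNA 25 and 70.0% ± 2.21 with crRNA 26 (SD, n = 3 each; exact permutation test between crRNAs, p = 0.0393). The crRNA accounted for a share of 0.559 of the variance. The difference between crRNAs did not pass the test with equal list lengths (exact permutation p = 0.264) or when permuting only within replicate numbers (exact permutation p = 0.0833). It also missed the threshold without any 1 of the 7 samples other than replicates 1 and 3 of HBE (exact permutation p between 0.0714 and 0.175). In those fits the share of variance stayed between 0.513 and 0.614. Regions called in 1 sample were near a gene boundary in 44.3% of cases (95% Wilson interval 42.7 to 46.0), and regions called in all 9 samples in 73.4% (68.2 to 77.9).

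Among 10 lists of genes fixed before the data were examined, the replication-dependent histone genes were over-represented near peaks called with every crRNA. A peak lay within 1 kb of 7 of 56 histone genes in at least 2 of 3 samples of each crRNA (12.5%, against 2.28% of other protein-coding genes; Fisher's exact test, adjusted p = 0.00292 over 10 lists). The genes were H1-2, H3C2, H1-4, H3C10, H3C1, H2AC4 and H4C1, all on chromosome 6, and because neighbours share peaks they rest on 6 regions. H1-2 had the best ranks, with a fold enrichment of 11.7 ± 2.01 in 9 of 9 samples. The call was lost without replicate 1 or replicate 3 of crRNA 26, with 2 genes called in both cases (Fisher's exact test, adjusted p = 1 and 0.915). A gene then needs both remaining samples of crRNA 26, which is a stricter rule. Under that rule 7 genes were called without replicate 2 of crRNA 26. It was also lost with a −log10 q of at least 5, with 4 genes (Fisher's exact test, adjusted p = 0.0915).

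The other lists did not pass. Short non-coding RNA genes had 7 of 32 members called (21.9%, against 8.33% of other genes of their classes; Fisher's exact test, p = 0.0361, adjusted p = 0.181), on 6 regions, among them the spliceosomal RNA genes RNU5E-1 (9.69 ± 4.11), RNU4-1 (7.66 ± 2.44) and RNU5D-1 (6.38 ± 1.33) and the histone pre-mRNA processing RNA gene RNU7-1 (9.02 ± 4.58), each in 9 of 9 samples. Numbered zinc-finger genes, taken over the gene body, had 3 of 509 (ZNF503, ZNF518A and ZNF391). Abundantly transcribed housekeeping genes had 1 of 26, the pyruvate kinase gene PKM. No member was called in at least 2 of 3 samples of every crRNA for the β-globin cluster (0 of 5), the IL1 cluster (0 of 9), ribosomal protein genes (0 of 77), heat shock genes (0 of 18), human promoters common in expression plasmids (0 of 11) or genes restricted to other tissues (0 of 30), each with an adjusted p = 1 in Fisher's exact test. The IL1RN peak does not enter its list, which asks for a call with every crRNA.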

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

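Of 379 alternative values, 317 kept their direction and side of the threshold, or stayed within 1.5 times the count, and 0 reversed. Of these, 150 concern single gene lists (145 kept), most of them with no member called, and the on-target values are all 0 or 1, so the tally says little about stability. A peak inside IL1RN in 6 of 6 samples and no peak at HBE1 held under each setting tried, and the share of called samples at IL1RN was 1 with all 6 IL1RN samples against HBE (exact permutation p = 0.0119, chosen after the data were seen). Leaving out a replicate gave 1 to 1 for that share and 0 to 0 at HBE1. For counts of regions or genes, leaving out a replicate also changes the rule, as described above. Of the settings below, the strict q value with full absence elsewhere, the comparison with the other IL1RN crRNA only, the lists shortened to 1507 peaks, the longest lists at one length, the local shift and the gene lists without a replicate were also chosen after the data were seen. The cause of these changes was not tested.

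Regions specific to HBE numbered 778 in at least 2 of 3 samples (highest other split 782), 41 at a −log10 q of at least 10 (highest other 34), 12 at equal list length, 46 with lists shortened to 1507 peaks, 29 and 39 with the 8 and 7 longest lists at one length, and 5 when strong and absent elsewhere, and ranged from 157 to 693 when a replicate was left out. Those of crRNA 25 numbered 24 in at least 2 of 3 samples, 0 at a −log10 q of at least 5, 1 at 10, 0 when strong and 17 against crRNA 26 only, ranging from 3 to 14 without a replicate. Those of crRNA 26 numbered 10, 2 at equal list length and 6 against crRNA 25 only, ranging from 0 to 6. Regions of both IL1RN crRNAs numbered 10 in at least 2 of 3 samples of each and 6 at equal list length (highest other split 5), of which 1 had no peak in the whole HBE lists, and ranged from 1 to 5. Regions called in all samples fell from 319 to 176 and 40 with a −log10 q of at least 5 and 10 and to 143 at equal list length (320 to 404 without a replicate). Those in at least 2 of 3 samples of every crRNA fell from 702 to 454, 151 and 307 (431 to 690, the lowest values being 431 and 459 without replicates 3 and 1 of crRNA 26).

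The difference in Jaccard index passed the test at equal list length (0.0382) and ranged from 0.0258 to 0.0795 without a replicate. The share of variance in peak number ranged from 0.415 to 0.791. The share of variance between crRNAs in peaks near gene boundaries missed the threshold within 2 kb (0.331, exact permutation p = 0.3), at a −log10 q of at least 5 (0.389) and 10 (0.499) and at equal list length (0.362), and ranged from 0.513 to 0.680 without a replicate. The ratio to random placements ranged from 10.6 to 11 without a replicate, and was 6.47 within 2 kb, 22.1 for protein-coding genes only, 8.09 against local shifts and 11.3 at a −log10 q of at least 10. The number of gene lists past the threshold was 0 at a −log10 q of at least 5 and 10 and with 3 of 3 samples of every crRNA, and 0 to 1 without a replicate, 0 without replicate 1 or 3 of crRNA 26.

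Replicate numbers did not pair the samples. The correlation of deviations was −0.0391 to 0.0638 for samples of the same number and −0.0771 to 0.0606 for others, and 4 of 9 samples correlated best with their own number. With the replicate block, the boundary share between crRNAs (0.559) had an exact permutation p = 0.0833. The block changed no other side of the threshold, though the on-target comparison then has a smallest p of 0.125. Depth is unknown, so whether a missing peak reflects few reads was not determined.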

Other observations

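Among the tests given here, those chosen only after the results they concern were seen are those of the rank of the HBE regions, of lists shortened to 1507 peaks, of the longest lists at one length with the regions left over, of IL1RN in the HBE lists, and of the strict q value for strong IL1RN regions; the counts over all splits were planned, but how to read them was set after they were seen.

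Transfer RNA genes, short genes read by RNA polymerase III, lay near more of the called regions than random positions would give. Of the 318 regions called in all 9 samples and placed on a chromosome, 16 had their summit within 1 kb of a tRNA gene, while 100 random placements gave 0.11 on average and at most 1. Placing the regions at random gene boundaries gave at most 2. Among the 150 regions found only in the HBE samples, 10 lay near a tRNA gene, against at most 1 by random placement and at most 2 by random gene boundaries. These are the sets with the highest shares, 5.02% of the regions called in all 9 samples and 6.67% of those of HBE. Over all 6631 regions the share was 2.22%. By number of samples, the other shares ran from 1.12% for regions called in 8 samples to 4.14% for those called in 5. Regions called in 3 samples, the class that holds the HBE regions, had 3.83%, and those called in 2 samples had 3.35%.

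The heavy chain locus IGH held 3 regions called in all 9 samples, each beyond the upper end of a constant gene on chromosome 14. The summits lay 3745 bp from IGHM, 3255 bp from IGHA1 and 2776 bp from IGHA2, the last being chosen after its values were seen. They ranked 1 to 3, 2 to 16 and 6 to 236 in the lists. A further region, 1843 bp beyond IGHE, was called in 7 samples. Repetitive switch regions for antibody class switching lie before the constant genes of this locus, and no genome sequence was at hand to compare them with the peaks.

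Of the 84 splits, only the real one gave as many as the 150 regions found in the 3 HBE samples and in no IL1RN sample. A split drawn at random would therefore rarely reach that count. The highest other gave 98 and took the 3 longest lists, replicates 2 and 3 of HBE and replicate 3 of crRNA 25. Counted in at least 2 of 3 samples, another split gave 782 against 778 for HBE. The number of peaks listed does not by itself account for a part of the 150. With the 7 longest lists taken at 1257 peaks each, the HBE samples had 39 such regions against 22 in the highest other of 35 splits. Of the 39, 23 had no peak in any whole IL1RN list. Lists of equal length can still differ in depth, which is unknown, so a difference in depth was not excluded. Other lengths decide less, as lists shortened to 1507 peaks gave 46 but left 4 IL1RN lists shorter still, and 686 peaks per sample gave 12 against 7 in the highest other split, which met the bound set earlier for excluding list length, a bound that was wrong because only 2 of the 12 belong to the 150. For the 127 regions not found at equal length, longer lists and an effect of the HBE crRNA cannot be told apart. The test for crRNA-directed binding as strong as at IL1RN found 0 of the regions among the 10 best peaks of each HBE list. For the 23 regions, weaker binding directed by the HBE crRNA may be an explanation. A difference in depth and an unlabelled difference in preparation that moves with the HBE samples are others, and none of these was tested. Of the 150 regions, 63.3% lay within 1 kb of a gene boundary (95% Wilson interval 55.4 to 70.6). Among all regions called in 3 samples, the class that holds them, the share was 67.2% (63.2 to 71.0), so they were not nearer to genes than that class. It was 55.1% of all regions and 73.4% of those called in all 9 samples.

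The HBE samples had no peak at HBE1. The HBE lists did not lack regions in general, as each called at least 94.4% of the 340 regions outside IL1RN that all 6 IL1RN lists share. Those regions do not follow the crRNA, so they cannot show the yield of the HBE samples at a site matched by the crRNA. A lower yield at such a site therefore stays open. A wrong label of the kind IL1RN crRNA in the libraries labelled HBE is excluded, with 0 of 3 HBE lists calling IL1RN. Sequence at the HBE1 locus left out by the authors' mask also stays open, as 0 peaks within 50 kb in 9 lists fit both a mask and an absence of binding. Weak or absent binding at HBE1 therefore may explain the lists as well as a mask does.

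The 319 regions called in all 9 samples do not follow the crRNA. For human sequences carried by the transfected plasmids, 0% of them lie within 1 kb of a gene on the plasmid list, but with 11 genes that list was too short to reach the share asked for, so this stays open. RN7SK and RPPH1 of that list, chosen after their values were seen, were each called in 5 of 9 samples. Whether the regions are background of the anti-FLAG precipitation at transcribed genes or Cascade bound without a crRNA match cannot be told apart, since 0 lists here come from cells without Cascade.

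For both IL1RN crRNAs together, 44 of 84 splits gave as many regions (1 region, highest other 20). For crRNA 25, 29 of 84 did (3 regions, highest other 150). List length differs between the splits, and the split with 20 took replicates 2 and 3 of HBE among its 6 samples. At equal list length both crRNAs had 6 regions, against 5 in the highest other split. Only 1 of those 6 had no peak in the whole HBE lists. These counts therefore cannot decide whether the grouping of samples alone would give such regions. For crRNA 26 the count was 0, which all 84 splits reach whatever the data (highest other 150), so nothing follows from it. The split that gave 150 is the one of the 3 HBE samples. With a −log10 q of at least 10 in all 6 samples, 1 of 84 splits gave 1 region, the real one with IL1RN, and the highest other gave 0.

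The other contigs and the mitochondrial genome held few peaks, with 3 to 12 per sample on unplaced contigs and 1 mitochondrial peak in replicate 3 of crRNA 26.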
